A study of Homo sapiens with 2 samples.

How the data were processed

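ChIP-seq with an anti-myc-tag antibody was carried out in CCLP1 cells infected with myc-PRH adenovirus or empty adenovirus, 1 library per group, per the labels. Chromatin was cross-linked with formaldehyde and sheared by sonication before precipitation, per the labels' protocols. Trim Galore, Bowtie2, MACS2 and the hg19 build are named in the submitters' processing notes, without versions or settings. The deposited table held 7532 peaks numbered without gaps, and no peaks overlapped. Its peak names begin with the name of the MACS2 caller, per the file headers and peak names, and its columns follow the layout of the HOMER annotation program as run through the ChIPseek web server.

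The deposited score of each peak is a whole number, and the quantity it stands for is not given in the sources used here. The table held no fold enrichment, pileup, p-value or q-value, so the score took the place of the planned fold enrichment wherever peaks were ranked, and the planned limits on q, fold enrichment and pileup were not applied. Coordinates and signed distances to the nearest TSS are the authors' other values, in bp on hg19, per the file headers. The header names no sample, so the list was read as the myc-PRH library called over the empty-adenovirus library, as the labels describe the design. The signal of the empty-adenovirus library on its own was not analysed here. Depth is unknown, and with 1 library per group no error between replicates can be given.

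Peaks were counted per annotation class, chromosome and distance bin, with exact Clopper-Pearson 95% intervals for shares. Gene names came from the deposited table. A gene table of assembly GRCh38.p14 served only to match symbols and transcripts (2917 of 2927 assigned genes matched, and 5111 of 5163 peaks with a transcript in their annotation), and none of its coordinates were used. The background was 19212 protein-coding genes, which leaves out unnamed gene models and genes with identifiers later than the highest in the deposited table. Of these 844 genes, 811 were left out by identifier and so could not have a peak, and the other 33, unnamed models, had 0. This restriction was made after results against all 20056 protein-coding genes had been seen, and both results are given.

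The 16 gene lists (555 entries, all matched) were fixed before the data were examined, from textbook knowledge, as were the tests, the window of 5000 bp and the threshold of 0.05. For each list, genes with a peak within the window were compared with all other background genes by a two-sided Fisher exact test. A peak counted only for the gene the deposited table assigned it to, that of the nearest TSS. Genes with any assigned peak were compared with 10000 random lists of the same size, a two-sided permutation test. Both used Benjamini-Hochberg adjustment over the 16 lists. The planned matching on gene span was not done, because spans of the files' build were not used here. Score and distance were compared by Spearman's rho with 100000 permutations and by Fisher's exact test between the highest and lowest of 4 score groups separated at the quartiles. The planned test of chromosomes needs hg19 lengths and the planned test of homeodomain motifs needs the hg19 sequence, and neither was run.

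Named genes followed a rule fixed beforehand: the 10 genes with the highest-scoring peaks, the 10 genes with the most assigned peaks, up to 4 members per list with a peak within the window by score, and 19 genes always named. CEBPB and other list members outside this rule were named after their values were seen, as were DST, VMP1 and HMGA2. Alternatives were windows of 1000 and 10000 bp, upstream peaks only, a background of genes with any peak, merging of overlapping peaks, and assembled chromosomes only. Alternatives chosen after seeing the data were the higher-scoring 3766 peaks, scores of 50 or more, leaving out chromosome 17, the strongest peak per gene, the background of all protein-coding genes, assignment by gene body, and HOX genes outside the HOXB cluster. Assignment by gene body took the transcript named in a peak's annotation. It therefore also counted peaks of the promoter and transcription termination site classes.

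The list tests were tested on simulated data with 19212 genes and the ribosomal protein list given 5 times the usual share of genes with a peak. The list was recovered in 97% of 100 simulations by Fisher's test and in 94% by random lists, and 0.133% and 0% of the other lists were called. Genes were drawn independently, at the share with a peak within 5000 bp, and only this list was raised. These rates therefore do not cover clustered genes, smaller lists or the count of any assigned peak. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.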

Results

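Genome occupancy of the homeodomain transcription factor PRH, the product of the HHEX gene, was profiled by ChIP-seq in CCLP1, an established human cholangiocarcinoma (bile duct cancer) cell line. Cells were infected with an adenovirus carrying myc-tagged PRH or with an empty adenovirus, and chromatin was precipitated with an antibody against the myc tag. The 2 groups held 1 library each, and the empty-adenovirus library served as background, per the labels. The deposited peak list described the myc-PRH library over that background, so no value below has a replicate, no difference between the conditions was tested, and every test compares genes or peaks within this list. Peaks and genes are not independent replicates. Sequencing depth is unknown here, and the intervals given cover counting error only.

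The strongest peak of the list was assigned to NRARP, which encodes a feedback inhibitor of Notch signalling. It lay on chromosome 9 from 140222636 to 140223016 (hg19), at −26123 bp from the NRARP transcription start site (TSS) and inside intron 17 of 21 of EXD3, with a score of 191. A peak in intron 1 of 18 of SMURF2, a ubiquitin ligase acting on the TGF-β pathway, followed with a score of 181 (chromosome 17, 62604319 to 62605317). The next was in intron 9 of 56 of TRIO, with a score of 176 (chromosome 5, 14328131 to 14328689). The score is the authors' own value for each peak; the quantity behind it is not given in the sources used here, and it is used only to rank and filter peaks within this list.

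In all, 7532 peaks were listed, with a median width of 352 bp (236 to 3271 bp) and a total length of 3229.96 kb. Scores ran from 13 to 191 with a median of 36, and 97 peaks scored 100 or more. Among the 10 genes with the highest-scoring peaks, LMNB2, which encodes the nuclear lamin B2, was the one whose strongest peak was of the promoter class, at −674 bp from its TSS (chromosome 19, 2457453 to 2457827, score 155). The peak of HEXIM1, an inhibitor of the transcription elongation factor P-TEFb, lay in its 3′ UTR at 3960 bp (chromosome 17, 43227832 to 43229455, score 146). TRPS1 (score 152), SBNO2 (151) and TNFRSF19 (148) had intronic peaks. The 2 remaining peaks lay inside another gene than the one assigned: MIR1203 (168) in intron 4 of 12 of SKAP1, and PTRH2 (141) in the 3′ UTR of CLTC.

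Many peaks carried the names of a small number of genes. TRIO was assigned 58 peaks, SMURF2 and TSC22D2 48 each, CDK17 42, EML4 39, SPAG9 38, KRR1 36, SEMA3C 35, SLC4A7 32 and ZBTB20 31. Not all of these lie over the gene named: the strongest peaks assigned to KRR1 and SEMA3C were intergenic, at −194336 and −239485 bp. Counted by gene body, however, SEMA3C held 35 peaks, with a highest score of 81 against 75 for that assigned peak. Counts by gene body, here and below, go by the transcript named in a peak's annotation. They include peaks in the classes of promoters and transcription termination sites, which can lie outside the gene. The 121 genes with 10 or more assigned peaks held 2232 peaks (29.6%), while 1684 genes had 1 peak. These counts per gene, and those by gene body below, were not adjusted for gene length, so long genes have more room for peaks. Of the 2980 bins of 100 kb that held a peak, 370 held 5 or more, and these contained 3334 peaks (44.3%). The densest such bin, on chromosome 3 from 150100000 to 150199999 around TSC22D2, held 44. By this count 59 peaks fell to TRIO, 56 to EML4, 50 to SMURF2 and 49 to DST, which encodes the cytoskeletal linker dystonin. Nearest-TSS assignment gave another name to some clusters: the 40 peaks counted for VMP1 most often carried the name of the microRNA gene MIR21, and the 38 counted for HMGA2, which encodes an architectural chromatin protein, that of RPSAP52.

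The genomic position of the peaks was examined next. Introns held 4121 peaks (54.7%, exact Clopper-Pearson 95% interval 53.6 to 55.8%) and intergenic sequence 2369 (31.5%, 30.4 to 32.5%). The class of transcription termination sites held 402 peaks (5.34%), 3′ UTRs 277 (3.68%) and promoters 230 (3.05%, 2.68 to 3.47%). Exons held 70 peaks, non-coding transcripts 59 and 5′ UTRs 4. Within 5000 bp of a TSS lay 1725 peaks (22.9%, 22.0 to 23.9%), and within 1000 bp 303 (4.02%). The median distance without regard to side was 18924 bp, and 65.3% of peaks lay downstream of, or at, the assigned TSS. Around the TSS the count per 1 kb was 270 from −2 to −1 kb, 198 from −1 to 0 kb, 105 from 0 to 1 kb and 230 from 1 to 2 kb.

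**Figure D1:**
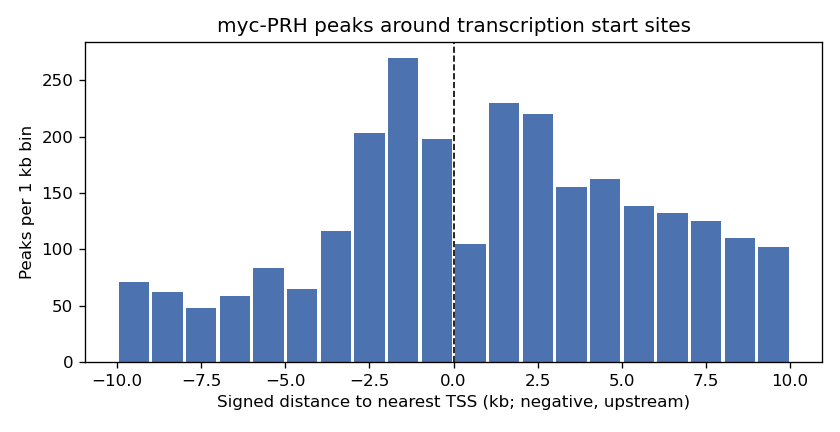
Number of peaks per 1 kb bin (vertical axis) against signed distance to the nearest TSS in kb (horizontal axis, negative upstream, dashed line at the TSS) for the single myc-PRH peak list. The bin from 0 to 1 kb held 105 peaks, fewer than the bins from −2 to −1 kb (270) and from 1 to 2 kb (230).

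Peaks were unevenly spread over chromosomes. Chromosome 17 held 816 (10.8%), or 10.1 per Mb between its first and last peak, against 3.63 per Mb on chromosome 12, 3.35 on chromosome 5, 3.25 on chromosome 1 and 0.403 on chromosome 4, which held 75. On chromosome 17 the 1 Mb bin starting at 62 Mb, which includes SMURF2, held 86 peaks, and those at 57 Mb (VMP1 and PTRH2) and 46 Mb (SKAP1 and the HOXB genes) held 76 and 65. The bin at 14 Mb of chromosome 5 (TRIO) held 67. No test was applied to chromosomes, because the lengths of the hg19 sequences were not used here.

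**Figure D2:**
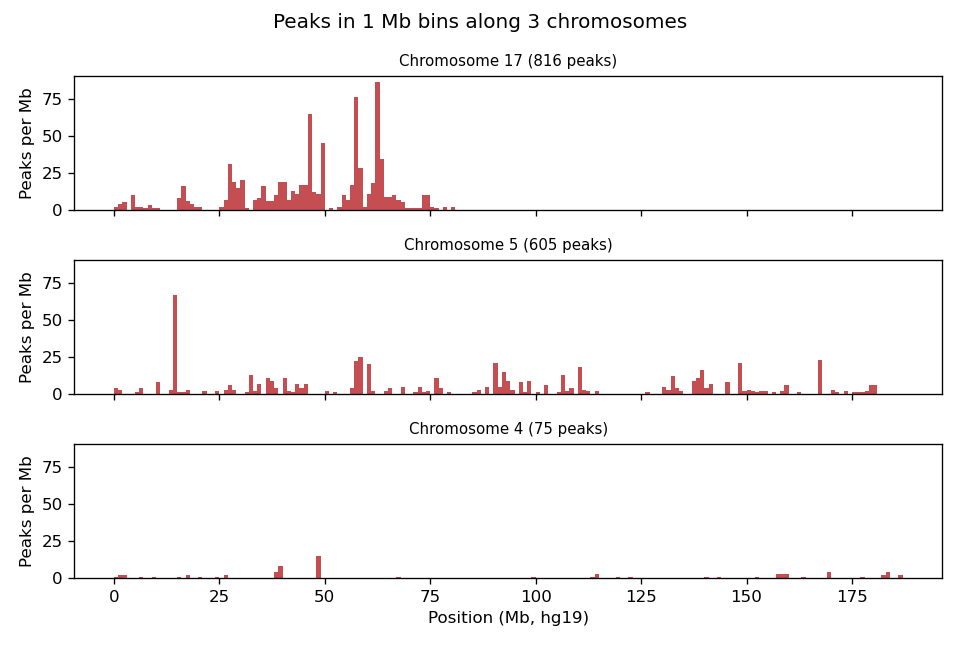
Peaks per 1 Mb bin (vertical axis) along chromosomes 17, 5 and 4 (horizontal axis, position in Mb, hg19) in the single myc-PRH peak list, on a common scale. Chromosome 17 reached 86 peaks in a bin and chromosome 5 reached 67, while the whole of chromosome 4 held 75.

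Higher-scoring peaks lay slightly more often near a TSS. The share within 5000 bp was 19.8% (18.3 to 21.5%) for scores of 13 to 28, 22.1% for 29 to 36, 24.7% for 37 to 48 and 26.6% (24.5 to 28.8%) for 49 to 191. The odds ratio between the highest and the lowest of these score groups was 1.46 (two-sided Fisher exact p = 4.6e-07). Across peaks, Spearman's rho between score and absolute distance was −0.0459 (permutation p = 7e-05, 100000 permutations). With only the strongest peak of each gene, rho was −0.0174 (permutation p = 0.342), whereas the difference between the highest and lowest score groups was 7.65 percentage points (Fisher exact p = 0.00191), against 6.72 with all peaks.

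Genes with a peak near a TSS were then compared with 16 gene lists. Each peak counted only for the gene with the nearest TSS, here and below, so a close peak nearer another TSS was missed. RPL12 and RPS20, for example, each held a peak by gene body (scores 57 and 48) but had none assigned. Of 19212 protein-coding genes, 935 (4.87%) had an assigned peak within 5000 bp. The cytosolic ribosomal proteins, chosen as a control list with open promoters, had such a peak at 15 of 56 genes (26.8%, 15.8 to 40.3%), against 4.80% of other genes (odds ratio 7.25, two-sided Fisher exact p = 4.54e-08, adjusted p = 7.26e-07 by Benjamini-Hochberg over 16 lists). This was the one list past the 0.05 threshold. The highest-scoring peaks among them were at RPL23 (score 91, at −267 bp), RPL27 (76, at −911 bp), RPL15 (75, at 3607 bp) and RPS6 (75, at 4151 bp), the last 2 in the class of transcription termination sites. The list did not pass with a window of 1000 bp (3.57% against 1.09% of other genes, adjusted exact p = 0.5) or with upstream peaks only (8.93% against 2.91%, adjusted exact p = 0.116).

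**Figure D3:**
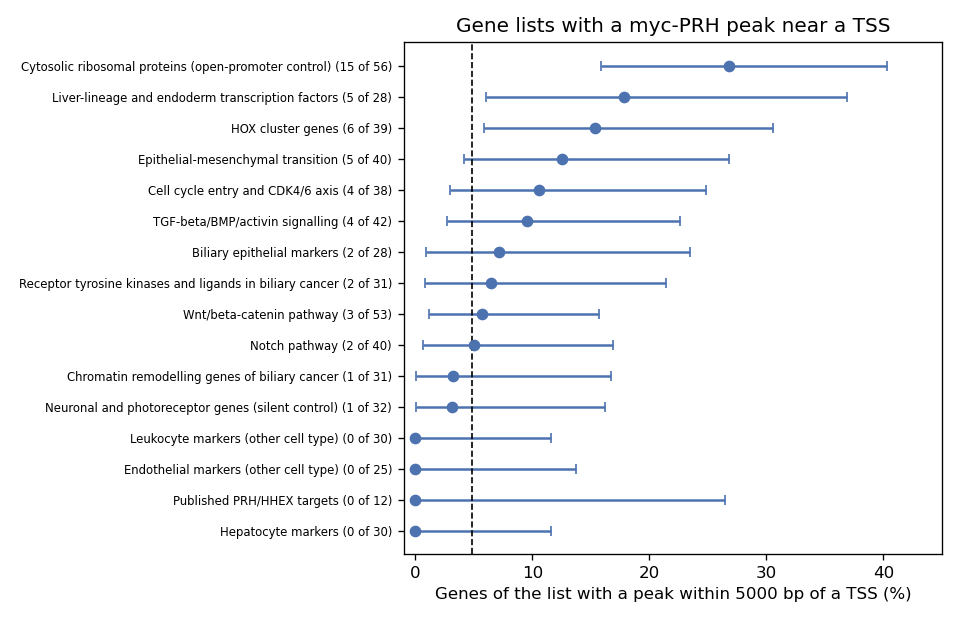
Percentage of genes in each of 16 lists with an assigned peak within 5000 bp of a TSS (points, horizontal axis) with exact 95% binomial intervals (bars). The dashed line marks the 4.87% of all 19212 genes. Ribosomal protein genes stand at 26.8%, and the published PRH targets and the hepatocyte, endothelial and leukocyte markers at 0.

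Liver-lineage and endoderm transcription factors had a peak within 5000 bp at 5 of 28 genes (17.9%, 6.06 to 36.9%). These were KLF5 (score 81, at −874 bp), YAP1, the Hippo pathway coactivator (59, at −258 bp), KLF6 (44, at −2145 bp), the YAP1 partner TEAD1 (28, at −1965 bp) and CEBPB. HOX cluster genes had one at 6 of 39 (15.4%, 5.86 to 30.5%), among them HOXB2 (105), HOXB8 (84), HOXC5 (67) and HOXB5 (67). Neither list passed the threshold (Fisher exact p = 0.0104 and 0.0108, adjusted p = 0.0575 for both). In an earlier run against all 20056 protein-coding genes of the gene table both had passed (adjusted exact p = 0.0471). The background was narrowed after those results were seen, to leave out 844 genes without a peak, of which 811 have identifiers later than any in the deposited table, so that they lack a peak by construction, and 33 are unnamed models. Outside the HOXB cluster, 3 of 29 HOX genes had such a peak (10.3%, 2.19 to 27.4%, against 4.85% of other genes, adjusted exact p = 0.439). With scores of 50 or more the whole HOX list passed (10.3%, adjusted exact p = 0.0232).

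Genes of the epithelial-mesenchymal transition had a peak within 5000 bp at 5 of 40 (12.5%, Fisher exact p = 0.0434, adjusted p = 0.174). They included the collagen genes COL1A2 (score 53, at −2000 bp) and COL3A1 (52, at −2862 bp), the tight-junction gene OCLN (44, at −923 bp) and the transcriptional repressor ZEB1 (36, at 1824 bp). The list passed with a window of 10000 bp (20%, adjusted exact p = 0.0338). Cell cycle entry genes had 4 of 38 (10.5%, adjusted exact p = 0.358). These were the replication licensing factor CDC6 (61, at −945 bp), the cyclin CCNE2 (51), E2F5 (32) and the CDK inhibitor CDKN1B (21). Counted by gene body, CDKN1B held 2 peaks, the strongest with a score of 72. TGF-β, BMP and activin signalling genes had 4 of 42 (9.52%, adjusted exact p = 0.39): TGFB2 (60, at −1272 bp), SMURF2 (57), BMPR2 (48) and ID3 (28).

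The Notch pathway, named in the title of the series, had a peak within 5000 bp at 2 of 40 genes (5%, 0.611 to 16.9%), a share close to the 4.87% of other genes (adjusted exact p = 0.915). These were the coactivator MAML1 (score 84, at −2002 bp, in the 3′ UTR of the neighbouring gene CANX) and RBPJ, the DNA-binding partner of Notch (26, at 1813 bp). The Wnt/β-catenin list had 3 of 53 (5.66%, adjusted exact p = 0.915), at DKK1, GSK3B and WNT16. Receptor tyrosine kinases and ligands had 2 of 31 (6.45%, adjusted exact p = 0.915), at MET, the hepatocyte growth factor receptor (76, at 1496 bp), and NRG1. Biliary epithelial markers had 2 of 28 (7.14%, adjusted exact p = 0.713), at MMP7 and GGT1. Chromatin remodelling genes had 1 of 31, SUZ12, and the neuronal and photoreceptor genes, chosen as a silent control, 1 of 32, TBR1 (adjusted exact p = 1 for both).

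No gene of 4 lists had an assigned peak within 5000 bp. These were the published PRH targets (0 of 12, upper limit 26.5%), hepatocyte markers (0 of 30, upper limit 11.6%), endothelial markers (0 of 25, upper limit 13.7%) and leukocyte markers (0 of 30, upper limit 11.6%). Their adjusted p-values by Fisher's exact test were 1, 0.713, 0.915 and 0.713, and since a count of 0 is the lowest possible, lists of these sizes could not show fewer peaks than other genes.

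When a peak at any distance counted, 2345 genes (12.2%) had an assigned peak, and ribosomal protein genes again stood above random lists of the same size, with 20 of 56 (35.7%, adjusted permutation p = 0.0032, the smallest that 10000 random lists give). TGF-β, BMP and activin signalling followed with 11 of 42 genes (26.2%, permutation p = 0.0204, adjusted p = 0.163), among them TGFBR2 with 19 peaks and TGFB2 with 5. By gene body TGFBR2 and TGFB2 held 5 and 9 peaks, and the strongest peak assigned to TGFBR2 was intergenic at −359482 bp. The epithelial-mesenchymal transition list had 10 of 40 (25%, adjusted permutation p = 0.17), with 10 peaks assigned to TWIST1. Receptor tyrosine kinases and ligands had 8 of 31 (25.8%, adjusted permutation p = 0.177), with 21 peaks assigned to MET and 10 to NRG1, and cell cycle genes 9 of 38 (23.7%, adjusted permutation p = 0.177). Receptor tyrosine kinases and ligands passed with the scores limited to 50 or more (19.4%, adjusted permutation p = 0.0144), as did the liver-lineage factors and HOX genes (adjusted permutation p = 0.0296 for both). Counted by gene body, liver-lineage factors stood at 10.7% against 10.0% of other genes, and HOX genes outside the HOXB cluster stood at 10.3% by assigned peak against 12.2% (adjusted permutation p = 1 for both). This count was not matched on gene length, which nearest-gene assignment favours.

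The remaining lists did not pass by this count. HOX genes had 8 of 39 (adjusted permutation p = 0.354), liver-lineage factors 6 of 28 (0.376) and chromatin remodelling genes 6 of 31 (0.495). The Notch pathway had 6 of 40 (15%, adjusted permutation p = 0.761): NRARP, NOTCH2, MAML1, ADAM10, ADAM17 and RBPJ. MAML2 and SPEN had no assigned peak but held 6 (strongest score 62) and 2 peaks by gene body, while the NRARP peak lay in EXD3. Counted by gene body the list stood at 15%, against 10.0% of other genes (adjusted permutation p = 0.555). The Wnt/β-catenin list had 7 of 53 (adjusted permutation p = 0.938) and biliary markers 2 of 28 (0.723). Hepatocyte markers had 0 of 30 against a mean of 3.65 genes in random lists (permutation p = 0.0424, adjusted p = 0.17). Endothelial markers had 0 of 25 (adjusted permutation p = 0.177), published PRH targets 0 of 12 (0.567), leukocyte markers 1 of 30 (0.354) and neuronal and photoreceptor genes 2 of 32 (0.584).

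Genes fixed beforehand to be named with or without a peak were inspected one by one. They belong to the Notch, published PRH target, cell cycle, biliary, epithelial-mesenchymal transition and Wnt lists. No peak was assigned to NOTCH3 or lay in its body, and the same held for NOTCH1, HES1, JAG1 and HHEX itself. Of the 19 such genes, 17 had no assigned peak; the others were the CDK4/6 inhibitor CDKN2B and its target CDK6. The CDKN2B peak lay at −33725 bp, in intron 3 of 18 of CDKN2B-AS1 (chromosome 9, 22042908 to 22043166, score 44). CDK6 was assigned 1 peak (chromosome 7, 92395973 to 92396208, intron 3 of 7, score 21), while it held 6 peaks by gene body, the strongest with a score of 84. The other genes without an assigned peak were CDKN2A, CDK4, CCND1, VEGFA, KDR, ENG, SOX9, KRT19, CDH1, SNAI2, WNT5A and TCF7L2. None of the 19 had an assigned peak within 5000 bp of a TSS. A peak at any distance can carry a neighbour's name under nearest-TSS assignment, so a gene with 0 assigned peaks can still have one nearby.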

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

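Counts from the detailed annotation, which the comparisons above do not use, were chosen after the results were seen. This column named a repeat element for 2167 of the 7532 peaks (28.8%). The most frequent family was the L1 retrotransposon, with 754 peaks, of which 695 were in older L1M and 46 in primate L1P elements. Alu elements, the most numerous short interspersed repeats of the human genome, were named for 54 peaks (0.717%), fewer than the older MIR (299) and L2 (254) families. Simple repeats of the sequence (TA)n were named for 84 peaks. These counts drew attention as values above 0 in a column outside the main measurement. The share of the genome in each repeat was not used here, so no count can be read as more or fewer than chance, and no explanation was tested.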

How the results depend on the processing

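The score-limited peak sets, the removal of chromosome 17, the strongest peak per gene, assignment by gene body, HOX genes outside the HOXB cluster and the background of all protein-coding genes were chosen after seeing the data. Under the alternatives 194 values kept their direction and side of the threshold or stayed within their interval, 24 shares or counts moved, 22 list shares turned, 10 newly passed and 5 no longer passed. Limits on q, fold enrichment and pileup, the chromosome and motif tests and matching on gene span were not run. Merging overlaps and assembled chromosomes only changed nothing, since the list has no overlaps and no other sequences. No paired analysis was possible because each group has 1 library. Depth is unknown, so its limits on the list cannot be stated.

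With the 3766 higher-scoring peaks, or the 1643 scoring 50 or more, the share within 5000 bp was 25.2% and 26.5%, the promoter share 3.72% and 4.08%, the chromosome 17 share 12.7% and 16.4% and the intron share 53.2% and 49.3%. With the strongest peak per gene these were 31.4%, 5.47%, 9.74% and 48.5%. The rank correlation between score and distance (Spearman) was −0.00663, −0.023 and −0.0174 in these 3 sets (permutation p = 0.682, 0.346 and 0.342), which hold fewer peaks and, in the first 2, a narrower range of scores. Windows of 1000 and 10000 bp held 4.02% and 35.2% of peaks.

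The number of lists past the threshold by peaks within the window was 1, and it became 0 at 1000 bp and with upstream peaks, 3 at 10000 bp, 3 with all protein-coding genes, and 2 with either score limit. By any assigned peak it was 1, and became 2 and 4 with the score limits. Ribosomal proteins stood at 3.57% at 1000 bp, against 1.09% of other genes, and at 8.93% against 2.91% upstream (unadjusted Fisher exact p = 0.125 and 0.0238, adjusted p from 1.69e-07 to 0.5 over alternatives). Newly past the threshold were the transition list (20%) and liver-lineage factors (21.4%) at 10000 bp, and liver-lineage factors (17.9%) and HOX genes (15.4%) with all protein-coding genes. HOX genes also passed with the higher-scoring peaks (15.4%) and at 50 or more (10.3%). Their adjusted p over alternatives ran from 0.00832 to 0.761 (the last without chromosome 17, where the HOXB genes stay in the list but lose their peaks), that of liver-lineage factors from 0.0471 to 0.36 and that of the transition list from 0.0338 to 1. By any peak, receptor tyrosine kinases passed with both score limits (25.8% and 19.4%, adjusted p from 0.0144 to 0.202), and liver-lineage factors (17.9%) and HOX genes (15.4%) at 50 or more. The cause was not tested.

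In 22 values a list turned to the other side of the remaining genes, none with an unadjusted p under 0.05 on either side; apart from the HOX values, the cause was not tested. At 1000 bp the Notch, Wnt, TGF-β and biliary lists stood at 0%. At 10000 bp Wnt was 5.66% and receptor tyrosine kinases 6.45%. Against genes with any peak, where other genes stood at 39.9%, only list genes with an assigned peak remained. There Notch was 33.3% (2 of 6), TGF-β 36.4% (4 of 11), receptor tyrosine kinases 25% (2 of 8) and neuronal genes 50% (1 of 2). Upstream, Notch was 2.5%, Wnt 0% and neuronal genes 3.13%. With the higher-scoring peaks, Notch was 2.5%, Wnt 1.89% and neuronal genes 3.13%. At 50 or more, Wnt and biliary were 0%. By any peak, chromatin genes were 3.23% with each score limit and HOX genes 7.69% without chromosome 17, where the HOXB genes could not have a peak by construction. HOX genes outside the HOXB cluster stood at 10.3% by any peak, with the HOXB genes left out of the list.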

Other observations

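The tests in this part were chosen after the results were seen, except the one on HHEX. Genes grouped by the letters that open their symbols (148 families, Fisher exact tests with Benjamini-Hochberg adjustment) showed families with few peaks. Of 390 olfactory receptor genes, 3 had an assigned peak (0.769%, against 12.4% of other genes, adjusted exact p = 3.49e-16) and 0 had one within 5000 bp (adjusted exact p = 9.22e-07). Zinc finger genes with ZNF symbols had an assigned peak at 36 of 512 (7.03%, adjusted exact p = 0.00768), CYP genes, mostly cytochrome P450 enzymes, at 0 of 56 (adjusted exact p = 0.0414) and CD antigens at 2 of 91 (adjusted exact p = 0.0412). A-kinase anchoring proteins (AKAP) had one at 7 of 16 (43.8%, adjusted exact p = 0.0414). Within 5000 bp none of these 4 families passed (adjusted exact p = 0.233 for ZNF, 0.924 for CYP, 0.579 for CD and 0.235 for AKAP). Here too the count of any assigned peak was not matched on gene length, which nearest-gene assignment favours. Neighbouring genes of a family are also not independent. Genes with RPL symbols, which overlap the ribosomal list, had a peak within 5000 bp at 14 of 52 (adjusted exact p = 8.8e-06), while those with RPS symbols had one at 5 of 45 (11.1%, adjusted exact p = 0.924) and any assigned peak at 10 of 45 (adjusted exact p = 0.385). Grouping by opening letters also puts other genes, such as kinases with RPS symbols, into the RPS family, so it does not hold ribosomal proteins alone. The difference between these families was not tested.

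Histone cluster genes had a peak within 5000 bp at 20 of 70 (28.6%, 18.4 to 40.6%), against 4.78% of other genes (odds ratio 7.97, Fisher exact p = 7.28e-11), a set picked because its genes stood out, so the p overstates the evidence. The endothelial, leukocyte and hepatocyte marker lists had 0 of 85 genes with a peak within 5000 bp and 1 of 85 with any assigned peak (1.18%, against 12.3% of other genes). They were merged because each had stood at 0 within 5000 bp, and the neuronal list (1 of 32 within 5000 bp, 2 of 32 with any peak) was not included, so no p is given.

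A first pattern was the absence of peaks at HHEX. The adenovirus carries PRH coding sequence, and reads from it would pile up on HHEX exons. The number of peaks assigned to HHEX or lying inside it was 0, so no such peaks are in the list. Whether the peak caller or a later filter removed any is not given in the sources used here.

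A second pattern was the peaks at ribosomal protein genes: of their 24 peaks within 5000 bp, 2 (8.33%, upper limit 27.0%) lay within 1000 bp of the TSS, which argues against promoter binding as the source of most of these peaks. The share for other genes, 16.4%, lies within that interval, and the 2 promoter peaks, at RPL23 and RPL27, were the strongest, so promoter binding at these genes remains open. In exons or UTRs lay 6 of all 43 assigned peaks (14.0%, upper limit 27.9%), fewer than looked for if reads shared with processed pseudogenes gave most of them. This does not decide the question, because the count left out termination-site peaks and peaks named for neighbouring genes. It also took peaks of 1 gene as independent. The shares were smaller in the whole list, where 3′ UTRs held 3.68% of peaks, exons 0.929% and 5′ UTRs 0.0531%. A contribution of such reads at some of these genes therefore stays open. Of the 15 genes, 10 (66.7%) had a peak over 1000 bp downstream of the TSS, against 46.1% of the 920 other genes with a peak (Fisher exact p = 0.125), so signal over the body and 3′ end of transcribed genes is left open. This distance does not place a peak inside the gene. The strongest peaks of RPL15 and RPS6 were of the termination-site class, and that of RPLP1, at 4836 bp, was intergenic. Counted by peaks, 18 of the 24 lay over 1000 bp downstream, against 42.4% of those of other genes, but peaks of 1 gene are not independent. Transcription was not measured here, and binding of myc-PRH in gene bodies remains open and untested.

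The last pattern was the clustering over genes such as TRIO and SMURF2: in 100 kb bins with 5 or more peaks, a mean of 60.5% of the peaks of a bin lay inside genes, against 55.9% in other bins (permutation p = 0.0716), so signal over gene bodies is left open. Counted by peaks, 2159 of 3334 in the dense bins lay inside genes, against 56.5% elsewhere, but peaks of 1 bin are not independent. Here promoter and termination-site peaks did not count as inside genes. For copy-number gains, off chromosome 17 the 32 bins lying 3 Mb from the 16 densest 1 Mb bins held 0.99% as many peaks (medians 0.5 and 50.5, flank mean 3.97 against 2.37 per bin), which argues against gains several Mb wide as the whole cause, although bins picked as the densest have lower flanks by selection, and narrower gains stay open. On chromosome 17 the share was 14.9% (medians 10.5 and 70.5, flank mean 19.1), and the dense bins at 46 and 49 Mb flank each other (65 and 45 peaks), so wide gains cannot be told apart from local clustering there. The median gap between neighbours in the 100 kb bins was 2280.5 bp, between the bounds set for a broad domain split into many peaks and for separate sites, so these cannot be told apart. A response to myc-PRH at these genes remains open, since 1 library per condition gives it no test.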
